A study of Drosophila melanogaster with 24 samples.

How the data were processed

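The samples were 24 polyA RNA libraries of Drosophila melanogaster: the wandering larval imaginal disc, the antenna at 8 h and at 40 h after pupation, and the adult antenna, each from 3 genotypes. The genotypes, per the labels, were wild type, rn[tot] over the TM6 balancer chromosome (here heterozygote) and rn[tot] homozygotes (here mutant). rotund (rn) encodes a zinc-finger transcription factor. Each of the 12 combinations of stage and genotype had 2 libraries, and the labels do not say whether these came from separate animals, so a p-value here may measure technical spread in part. The heterozygote differs from the wild type in carrying TM6 and a different stock as well as in its rn allele.

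Per the labels' protocols, RNA was extracted with an RNeasy kit and made into stranded mRNA libraries for Illumina sequencing. Per the submitters' processing notes, the tools were CASAVA 1.8, BWA 0.7.12 and DESeq2, for which no version was given. The genome build, the program that counted reads, its strand setting and its treatment of reads shared between transcripts or genes are not given in the sources used here. A value can therefore hold reads of an overlapping or paralogous gene, as for Or19a and Or19b, Or22a and Or22b, Or65a to Or65c and the Hsp70 genes.

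The deposited unnormalized table holds counts for 29872 FlyBase transcripts. The deposited normalized table holds a signal that equals those counts times 1 constant per library, with a range of 0 between transcripts, so the counts were used for every value. Of the transcripts, 29393 were matched to 13409 genes of the Ensembl annotation of the BDGP6 assembly, whose coordinates are used throughout, covering 98.69% of all counts. The other 479 were left out. Transcripts of 1 gene share reads: over 2302 genes with a pair of well-counted transcripts, the median chi-squared per degree of freedom between them across libraries was 0.144, below what independent counting allows, and 6755 genes have several transcripts. Each gene was therefore given the count of its transcript with the highest total, which kept 45.5% of the summed counts. The sum over transcripts was an alternative. This choice was made after the table was seen, since a table of genes had been assumed. Counts per library ran from 17441575 to 33353768 over transcripts and from 8060184 to 15123676 over genes.

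Genes were tested with edgeR 4.0.16 in R 4.3.3: trimmed-mean normalization (TMM), filterByExpr with a minimum count of 10, and the quasi-likelihood F test in a design of 12 groups over all 24 libraries, with Benjamini-Hochberg adjustment at 0.05, two-sided. That left 10994 genes and 12 residual degrees of freedom, with a common dispersion of 0.0521 (a coefficient of variation of 22.8%) and 4.13 prior degrees of freedom. Levels are CPM, counts scaled to a common library size with TMM factors, and log CPM values used a prior count of 2. The comparisons were mutant against wild type, mutant against heterozygote and heterozygote against wild type at each stage, each step between successive stages in wild type, and the difference of the mutant effect between larva and 8 h and between 40 h and the adult. A gene differed from both controls when it passed against wild type and against heterozygote in the same direction.

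The tests, the alternatives, the gene lists and the rule for named genes were fixed before the data were examined. The rule took rn first. For each stage it took up to 10 higher and 10 lower genes that differed from both controls at 5 CPM or more, ranked by the smaller of the absolute log2 changes, and up to 4 members of each list. For the other comparisons it took 5 genes in each direction and up to 4 members of each list, and for the differences between stages the 5 smallest p-values.

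The 28 lists, with tested members of all members where these differ, were rn, proximodistal patterning factors (23), proneural and Notch genes (18 of 19), transcription factors of olfactory neuron fate (14 of 15), receptors of the large basiconic sensilla ab1 to ab3 (9 of 10), of the small basiconic sensilla ab4 to ab10 (16), of trichoid and intermediate sensilla (13), of the palp (4 of 7) and of the larva (6 of 13), ionotropic receptors of coeloconic sensilla (10) and of the arista and sacculus (6), chemosensory coreceptors (5), odorant-binding and support-cell genes (15), axon guidance genes (28), dpr and DIP cell-surface genes (30), pan-neuronal genes (10), glial genes (8), ecdysone response genes (10 of 11), cuticle genes (86 of 115), cell cycle genes (21), leg and homeotic genes (4 of 8), eye genes (14 of 16), muscle genes (13), fat body genes (8), hemocyte genes (9), heat shock genes (15), antimicrobial peptides (13 of 14) and sex-biased genes (6 of 8). Lists with at least 3 tested members were tested in the 8 mutant comparisons with camera of limma 3.58.1 at a preset correlation of 0.01, in 216 tests adjusted together. Camera compares a list with all other genes. Or10a, Or85d, Or94b, Dl, Eip71CD, Rh6, roX1 and roX2 were not analysed here.

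The alternatives fixed at that time were median-of-ratios (RLE) scaling, no low-count filter, DESeq2 1.42.0, only the libraries of the stages compared, the replicate number as a block, each library left out in turn, and camera with an estimated correlation. The sum over transcripts and the omission of 4 libraries in doubt were added after the data were seen. These were 8 h wild type library 1 and larval heterozygote library 1, with a high share of mitochondrial transcripts (3.82% and 3.05%, against 1.47% and 1.51% in library 2). The others were 40 h heterozygote library 1, where the 20 most abundant genes took 19.89% of counts against 14.96%, and adult mutant library 1, with Yp1 at 251.2 CPM against 35.96. Replicate numbers do not pair the libraries, since the correlation of residuals between groups by number lay between -0.139 and 0.089. Where a group had 0 counts, a fold is a lower bound against 3 counts over the group, and with 1 to 3 counts a ratio is given with its exact 95% interval. Such bounds and intervals cover counting error only, and they take counts as independent. Of transcript counts from 1 to 20, between 72.78% and 78.32% per library were even, so counts tended to come in pairs. The intervals are therefore too narrow and the bounds too high. Scaling by RLE or DESeq2 moved the median of all genes by 0.102 on the log2 scale for 40 h against 8 h and by 0.129 for adult against 40 h in wild type.

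Counts were simulated at the same depth, with the spread of each gene taken from the edgeR fit and shared by all groups. In these, 100 genes were changed by a factor of 2 and 100 by a factor of 4 in the adult mutant. There edgeR called 38 and 86 of them against wild type with 4 false calls, and 28 and 82 against both controls with 0. DESeq2 called 61 and 94 with 27 false calls. Since spread differed between groups in the data, these rates need not hold there, and the setting may favour edgeR. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 was used for tables and plots.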

Results

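Messenger RNA was measured in 24 libraries from the larval imaginal disc, the antenna at 8 h and 40 h after pupation and the adult antenna, in wild type, rn heterozygotes and rn mutants. Each of the 12 groups had n = 2 libraries. Gene counts ran from 8060184 to 15123676 per library. Levels below are mean ± SD in CPM over the 2 libraries of a group, log2 changes are ± SE, and adjusted p-values are from edgeR unless another tool is named. Stage was the main axis of variation: the leading 3 principal components, which separated the stages, held 55.8%, 22.7% and 11.6% of the variance. The mutant comparisons ask which transcripts depend on rn, the stage comparisons how the transcriptome changes from disc to adult antenna. Larval samples were labelled imaginal disc and later ones antenna. In the step from larva to 8 h, stage therefore cannot be told apart from the tissue dissected.

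rn mRNA was present in the disc and the young antenna, and low from 40 h on. In wild type its level was 42.7 and 43.69 CPM in the larval libraries, 127.3 and 79.26 CPM at 8 h, 2.151 and 3.02 CPM at 40 h, and 2.545 and 2.951 CPM in the adult. The step from 8 h to 40 h was -5.31 ± 0.33 (adjusted p = 1.64e-09). rn mRNA was not lost in the mutant: the mutant libraries held 74.68 and 68.7 CPM in the larva and 48.79 and 44.61 CPM at 8 h, where the change against wild type was -1.14 ± 0.26 (adjusted p = 0.0268). Without wild type library 1 at 8 h that change was -0.76 (adjusted p = 0.235), without mutant library 1 -1.21 (adjusted p = 0.154) and without mutant library 2 -1.08 (adjusted p = 0.196). Against the heterozygote it was -0.74 ± 0.26 (adjusted p = 0.768). The labels do not say what rn[tot] does to the rn transcript.

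**Figure D1:**
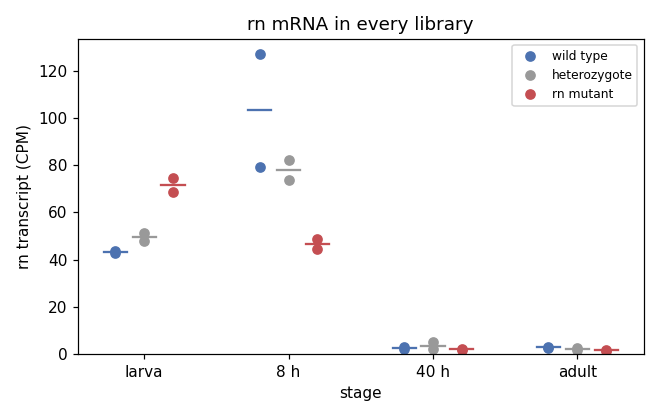
rn mRNA in CPM (vertical axis) by stage (horizontal axis), with 1 point per library, colour for genotype and a short line at each group mean. Mutant libraries at 8 h sit at 48.79 and 44.61 CPM, wild type libraries at 127.3 and 79.26 CPM, and all libraries at 40 h and in the adult at or below 4.98 CPM.

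In the larval disc, 8 genes separated the rn mutant from both controls, and most of them changed by a large factor. Map205, which encodes a microtubule-associated protein (FBgn0002645, 3R 32055279 to 32068441), stood at 473 ± 27.1 CPM in wild type, 333 ± 137 in heterozygotes and 6.22 ± 2.81 in mutants. Its change was -6.26 ± 0.42 against wild type (adjusted p = 2.17e-07) and -5.75 ± 0.41 against heterozygotes (adjusted p = 2.33e-06). CHKov1 (FBgn0045761, 3R 25323156 to 25329316) was at 82 ± 6.42, 53.4 ± 22.1 and 4.65 ± 0.35 CPM in the same order, with changes of -4.14 ± 0.34 and -3.52 ± 0.33. GstZ1, a glutathione S-transferase, was at 20.4 ± 4.59, 20.2 ± 9.68 and 0.31 ± 0.2 CPM. Ac3, an adenylyl cyclase (FBgn0023416, 2L 21632587 to 21647964), fell less, from 19.2 ± 1.96 and 18.8 ± 5 CPM to 7.02 ± 0.35 (-1.45 ± 0.27, adjusted p = 0.00694; -1.42 ± 0.27, adjusted p = 0.0431).

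The genes that were higher in the larval mutant were Calx, a sodium/calcium exchanger (FBgn0013995, 3R 20978183 to 21015613), its neighbour CG5697 (3R 21015949 to 21017120) and ATPsynepsilonL, a relative of the ATP synthase epsilon subunit. Calx rose from 0.26 ± 0.16 CPM in wild type and 2.77 ± 0.77 in heterozygotes to 12.2 ± 1.94 (5.55 ± 0.34, adjusted p = 1.01e-07; 2.14 ± 0.24, adjusted p = 0.000333). CG5697 had 3 counts in wild type, and the mutant level of 27.4 ± 1.98 CPM was 220 times that (counting interval 75.1 to 1070). ATPsynepsilonL was at 2.26 ± 0.16, 10.1 ± 0.1 and 70.8 ± 3.13 CPM. The remaining gene, CG34353, lay below 5 CPM and is named after its values were seen: it was at 3.09 CPM in wild type, 2.86 in heterozygotes and 0.397 in mutants. In each of these 8 genes both mutant libraries lay outside the range of the 4 control libraries.

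Among the fixed lists, no member differed from both controls in the larva. Against heterozygotes alone, camera placed hemocyte genes higher in the mutant (adjusted p = 8.3e-07; adjusted p = 0.00446 with an estimated correlation), with 0 of 9 members past the test over all genes and 3 adjusted over the list alone. Pxn, a hemocyte peroxidase, stood at 26.3 CPM in wild type, 6.84 in heterozygotes and 23.8 in mutants. Against the same control, heat shock genes were lower (adjusted p = 0.000185; adjusted p = 0.79 with an estimated correlation). So were axon guidance genes (adjusted p = 0.0343; adjusted p = 0.923 with an estimated correlation), fat body genes (adjusted p = 0.0387; adjusted p = 0.79 with an estimated correlation) and ab4 to ab10 receptors (adjusted p = 0.0364; adjusted p = 0.305 with an estimated correlation). Cuticle genes were higher there (adjusted p = 0.00238; adjusted p = 0.79 with an estimated correlation). Against wild type, fat body genes (adjusted p = 0.00715; adjusted p = 0.669 with an estimated correlation) and muscle genes (adjusted p = 0.0203; adjusted p = 0.839 with an estimated correlation) were lower. Of these lists, 0 of 8 and 0 of 13 members passed over all genes in edgeR, and 5 and 4 adjusted over the list alone. Mitochondrial transcripts took 3.05% of counts in heterozygote library 1 and 1.51% in library 2, with RpL35A at 40.2 and 1220 CPM and RpL8 at 95.4 and 2300 CPM. Without heterozygote library 1, camera again called hemocyte genes (adjusted p = 3.46e-08), heat shock genes (adjusted p = 3.31e-08) and ab4 to ab10 receptors (adjusted p = 0.0095) against heterozygotes. It did not call axon guidance genes (adjusted p = 0.872), fat body genes (adjusted p = 0.517) or cuticle genes (adjusted p = 0.0749). Across all genes, 88 were higher and 81 lower in mutants than in wild type, and 9 were higher and 9 lower than in heterozygotes. The total of 169 against wild type was 83 without wild type library 2, 91 without mutant library 1 and 88 without mutant library 2. That of 18 against heterozygotes was 9 without heterozygote library 1 or mutant library 1, 82 without heterozygote library 2 and 5 without mutant library 2. The count against both controls was 5 without heterozygote library 1, 4 without mutant library 1 and 3 without mutant library 2. ATPsynepsilonL, CG5697, Ac3, CG34353 and GstZ1 passed in 6, 7, 7, 10 and 11 of 13 alternatives, and the others in at least 12. In 10 sets of counts simulated without an effect, edgeR placed 0 genes apart from both controls at every stage. Their spread came from the edgeR fit and was shared by all groups, unlike that of the data.

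In the antenna at 8 h, 7 genes differed from both controls, and the losses of Map205, CHKov1 and GstZ1 were again seen. Map205 was at 728 ± 375 CPM in wild type, 230 ± 6.33 in heterozygotes and 5.06 ± 0.59 in mutants (-7.17 ± 0.44 and -5.51 ± 0.42). CHKov1 was at 55.2 ± 23.2, 20 ± 3.89 and 0.94 ± 0.34 CPM. GstZ1 had 0 counts in the mutant, at least 101-fold lower than in wild type and at least 61.1-fold lower than in heterozygotes. Calx was higher, at 0.50, 2.2 and 11.2 ± 1.8 CPM in wild type, heterozygotes and mutants (4.47 ± 0.33, adjusted p = 6.48e-07; 2.34 ± 0.25, adjusted p = 0.000256).

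CG9008 (FBgn0028540, 2L 13774340 to 13780165), CG34461 (FBgn0250833, 3L 8325859 to 8328307) and CG3726 (FBgn0029824, X 5917097 to 5941852) were lower in the 8 h mutant. CG9008 stood at 21 ± 5.34 CPM in wild type, 18.1 ± 3.15 in heterozygotes and 4.24 ± 0.27 in mutants (-2.30 ± 0.26, adjusted p = 7.21e-05; -2.09 ± 0.26, adjusted p = 0.000984). CG34461 was at 12.9 ± 1.09, 10.6 ± 2.44 and 1.27 ± 0.15 CPM, and CG3726 at 12.1 ± 1.62, 14.4 ± 2.27 and 3.94 ± 0.69 CPM. CG3726, CG34461, GstZ1 and CG9008 passed in 7, 9, 10 and 11 of 13 alternatives, and the others in 12. No member of a fixed list differed from both controls. The patterning factor bab1, which acts along the proximodistal axis of antenna and leg, was lower in mutants than in wild type, at 6.21 and 20.8 ± 5.14 CPM (-1.74 ± 0.22, adjusted p = 0.000245) with 10.1 in heterozygotes (mutant against heterozygote -0.70, adjusted p = 0.675).

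Axon guidance genes were lower in the 8 h mutant than in wild type by camera (adjusted p = 3.35e-05; adjusted p = 0.79 with an estimated correlation), with 3 of 28 members past the test over all genes and 14 adjusted over the list alone. CadN, an adhesion protein, was at 85.4 ± 48.4 CPM in wild type and 36.5 in mutants (-1.22 ± 0.31, adjusted p = 0.0391). That call was lost without wild type library 1 (-0.49, adjusted p = 0.641), mutant library 1 (adjusted p = 0.228) or mutant library 2 (adjusted p = 0.168). Without wild type library 1, in which mitochondrial transcripts took 3.82% of counts against 1.47% in library 2, 0 of the 28 members passed in edgeR, the list median moved from -0.50 to -0.17 on the log2 scale and camera did not call the list (adjusted p = 0.123). dpr and DIP genes were lower (adjusted p = 0.0412; adjusted p = 0.714 with an estimated correlation), with 3 of 30 members over all genes and 3 adjusted over the list alone. Without wild type library 1 none passed, the median moved from -0.78 to -0.27 and the list was not called (adjusted p = 0.144). Cuticle genes were higher (adjusted p = 0.0172; adjusted p = 0.862 with an estimated correlation), and without that library their median moved from 0.53 to 0.04 (adjusted p = 0.999). Antimicrobial peptides (adjusted p = 0.00103, and 0.0972 with all libraries) and cell cycle genes (adjusted p = 0.0338, and 0.432 with all libraries) were called lower against wild type only without it. Against heterozygotes, odorant-binding and support-cell genes were lower (adjusted p = 5.66e-08; adjusted p = 0.246 with an estimated correlation). Antimicrobial peptides (adjusted p = 8.25e-06; adjusted p = 0.266 with an estimated correlation) and cell cycle genes (adjusted p = 0.0231; adjusted p = 0.597 with an estimated correlation) were lower too. Coeloconic receptors (adjusted p = 0.000449; adjusted p = 0.144 with an estimated correlation) and axon guidance genes (adjusted p = 0.0417; adjusted p = 0.923 with an estimated correlation) were higher there.

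Across all genes at 8 h, 107 were higher and 262 lower in mutants than in wild type, 369 in all. That total was 144 without wild type library 1, with 74 higher and 70 lower, so the excess of lower genes rests on that library. It was 4800 without wild type library 2, 87 without mutant library 1 and 112 without mutant library 2. Against heterozygotes 2 were higher and 8 lower, and the total of 10 was 49 without heterozygote library 2, 5 without mutant library 1 and 6 without mutant library 2. The count against both controls was 11 without wild type library 1, 15 without wild type library 2 or heterozygote library 2, and 4 without mutant library 1 or 2. With only the 8 h libraries in the fit, edgeR called 0 genes for mutant against wild type, 8 h. At an unadjusted p under 0.05 that fit held 682 genes, and DESeq2 with all libraries called 1114. The main fit over all 24 libraries gives each gene 1 spread for all groups, while the 8 h wild type replicates lay furthest apart. Its p-values for the comparisons with wild type at 8 h can therefore be too small.

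At 40 h, when olfactory receptor genes begin to be expressed, the receptor Or67c (FBgn0036078, 3L 10243320 to 10244706) had 0 counts in the mutant. That was at least 17.4-fold lower than the wild type level of 2.51 ± 0.23 CPM (adjusted p = 0.00549). It was at least 53.2-fold lower than the heterozygote level of 7.6 ± 1.86 CPM (adjusted p = 0.00429). It was the single member of a fixed list to differ from both controls, 1 of 16 receptors of small basiconic sensilla. CHKov1 (112 ± 0.2, 33.2 ± 6.87 and 0.48 ± 0.14 CPM), GstZ1 (20.3, 7.78 and 0.29 CPM) and Map205 (628 ± 8.9, 241 ± 24.7 and 13.3 ± 4.39 CPM) were lower in mutants than in both controls. CG5697 and CG34138 (FBgn0083974, 3R 19634949 to 19635879) were higher, at 29.4 ± 3.9 and 62.8 ± 7.13 CPM in mutants against 1 ± 0.79 and 1.64 in wild type and 2.71 ± 1.69 and 17.6 ± 1.49 in heterozygotes.

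Ir21a, a cool-sensing receptor of the arista, was at 28.9 ± 5.38 CPM in wild type at 40 h, 3.34 in heterozygotes and 1.64 in mutants. The change against wild type was -4.13 ± 0.54 in mutants (adjusted p = 0.000348) and -3.11 ± 0.5 in heterozygotes (adjusted p = 0.00305). Arista and sacculus receptors were lower against wild type by camera (adjusted p = 0.0412; adjusted p = 0.246 with an estimated correlation), with Ir21a the 1 member of 6 that passed, over all genes and adjusted over the list alone. Against heterozygotes, odorant-binding and support-cell genes were lower (adjusted p = 5.51e-15; adjusted p = 0.0461 with an estimated correlation), with 0 of 15 past the test over all genes and 8 adjusted over the list alone. Chemosensory coreceptors were lower (adjusted p = 0.000449; adjusted p = 0.144 with an estimated correlation), as were cuticle genes (adjusted p = 0.00266; adjusted p = 0.79 with an estimated correlation). Muscle genes (adjusted p = 0.0302; adjusted p = 0.87 with an estimated correlation) and antimicrobial peptides (adjusted p = 0.0307; adjusted p = 0.73 with an estimated correlation) were lower. dpr and DIP genes were higher (adjusted p = 0.0336; adjusted p = 0.712 with an estimated correlation). The 20 most abundant genes took 19.89% of counts in heterozygote library 1 and 14.96% in library 2. Without heterozygote library 1 the calls for cuticle (adjusted p = 0.749), muscle (adjusted p = 0.428) and dpr and DIP genes (adjusted p = 0.667) were lost, and ab4 to ab10 receptors were called lower (adjusted p = 0.0176, and 0.052 with all libraries). Across all genes, 77 were higher and 65 lower than in wild type, and 4 higher and 5 lower than in heterozygotes. The 142 against wild type were 69 and 61 without wild type library 1 or 2 and 82 and 64 without mutant library 1 or 2. The 9 against heterozygotes were 21 without heterozygote library 2 and 3 without heterozygote library 1 or either mutant library. The count of 6 against both controls was 3 without heterozygote library 1, mutant library 1 or mutant library 2. GstZ1 and CG34138 passed in 6 of 13 alternatives, each losing the call without any of the 6 libraries of the stage, Or67c and CG5697 in 11, and Map205 and CHKov1 in all. Or67c lost its call without either mutant library.

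**Figure D2:**
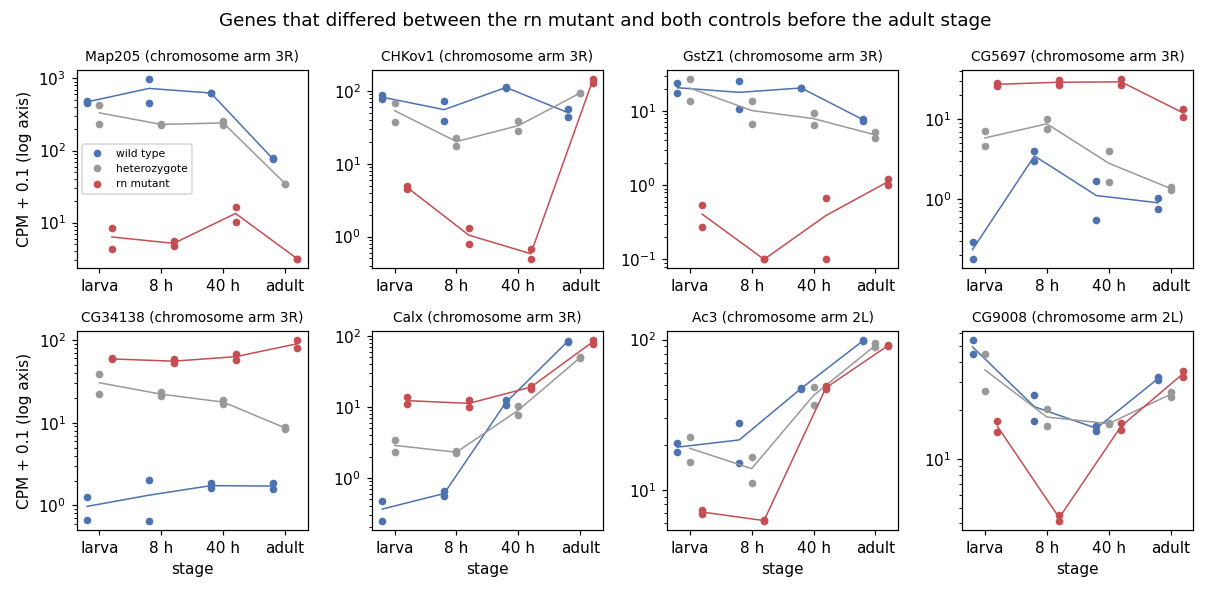
CPM plus 0.1 on a log axis (vertical) over the 4 stages (horizontal) for 8 genes, with 1 point per library and colour for genotype. Map205 in mutants stays at or below 13.3 CPM on average from larva to 40 h where wild type averages 473 to 728, while Ac3 and CG9008 separate in the larva and at 8 h.

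In the adult antenna, a subset of odorant receptor genes was nearly absent from the rn mutant, while others such as Or92a and Or22b were at similar levels in all genotypes. Or67d, a pheromone receptor (FBgn0036080, 3L 10273204 to 10274624), stood at 52.1 ± 0.98 CPM in wild type, 47.6 ± 4.8 in heterozygotes and 0.16 in mutants. Its change was -8.29 ± 0.5 against wild type (adjusted p = 3.06e-06) and -8.16 ± 0.5 against heterozygotes (adjusted p = 1.49e-05). Or67c had 2 counts in the mutant, against 28.6 ± 0.69 CPM in wild type (ratio 368, counting interval 101 to 3040) and 46.1 ± 7.52 in heterozygotes (ratio 597, counting interval 165 to 4940). Receptors named here and below that did not pass were chosen after their values were seen. Or92a was at 201, 187 and 193 CPM and Or22b at 140, 166 and 133 CPM in wild type, heterozygotes and mutants. The coreceptor Orco was at 2450, 2165 and 1675 CPM (adjusted p = 0.366 against wild type and 1 against heterozygotes).

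Of 16 receptors of the small basiconic sensilla, 6 differed from both controls, all lower: Or67c, Or47a, Or67a, Or98a, Or82a and Or85f. Or47a (FBgn0026386, 2R 11250368 to 11251913) was at 33.8 ± 0.83, 59.4 ± 0.17 and 0.27 ± 0.16 CPM (-6.90 ± 0.72, adjusted p = 3.82e-05; -7.72 ± 0.73, adjusted p = 3.75e-05). Or67a (FBgn0036009, 3L 9529067 to 9531386) was at 40.3 ± 6.01, 60.2 ± 2.13 and 0.31 CPM, and Or98a (FBgn0039551, 3R 27845950 to 27847260) at 34.4 ± 9.56, 64 ± 6.31 and 0.31 CPM. Or82a was at 26.4, 32.7 and 1.24 CPM, and Or85f at 15.2, 16.1 and 0.62 CPM. By camera the list was lower against wild type (adjusted p = 1.34e-22; adjusted p = 4.17e-05 with an estimated correlation) and against heterozygotes (adjusted p = 3.84e-66; adjusted p = 2.67e-07 with an estimated correlation). Against each control 6 members were lower over all genes and 7 adjusted over the list alone, and 1 was higher against wild type in each count. Or33b was the higher member, at 0.23 CPM in wild type, 7.44 in heterozygotes and 7.39 in mutants, and its call was lost without wild type library 1 (adjusted p = 0.0937) or 2 (adjusted p = 0.0597).

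Of 13 receptors in the fixed list of trichoid and intermediate sensilla, 5 were lower than in both controls: Or67d, Or19a, Or19b, Or43a and Or13a. That list includes Or13a, although the grouping by sensillum further below places it in ab6, a small basiconic sensillum. Or19a was at 36 ± 2.2, 32.8 ± 4.5 and 0.23 CPM, and its paralog Or19b at 37 ± 2.25, 32.9 ± 3.89 and 0.2 CPM. Or43a (FBgn0026389, 2R 7232840 to 7234913) was at 27.4 ± 3.19, 24.4 ± 1.38 and 0.23 CPM, and Or13a at 43.3 ± 2.19, 53.5 ± 1.04 and 1.4 ± 0.03 CPM. The list was lower by camera against wild type (adjusted p = 8.56e-16; adjusted p = 6.46e-05 with an estimated correlation). It was lower against heterozygotes as well (adjusted p = 4.1e-25; adjusted p = 1.18e-05 with an estimated correlation). Its median against wild type was 0.03 and its mean -2.75 on the log2 scale. Over all genes 6 members were lower against wild type and 5 against heterozygotes, and without mutant library 1 these were 5 and 2. Besides the 5 named, Or2a was lower against wild type, at 9.81 CPM there, 7.69 in heterozygotes and 0.777 in mutants (-3.64, adjusted p = 0.0252; -3.29 against heterozygotes, adjusted p = 0.235). That call was lost without any of the 4 libraries compared, at adjusted p between 0.0985 and 0.227. Or47b stood at 70.5 CPM in wild type, 87.8 in heterozygotes and 105.5 in mutants, and Or65a at 51.4, 21.7 and 58.6 CPM. Adjusted over the list alone, 6 members were lower against each control, and 2 higher against heterozygotes. No ab1 to ab3 receptor differed from both controls, and camera did not call that list.

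Receptors outside these classes changed too. The coeloconic receptor Ir92a was at 20.4 ± 0.84 CPM in wild type, 16.3 ± 1.11 in heterozygotes and 0.94 ± 0.46 in mutants (-4.43 ± 0.73, adjusted p = 0.00469; -4.11 ± 0.72, adjusted p = 0.0337). Or46a, a receptor of the palp, was at 14.5 ± 1.77, 15.3 ± 0.5 and 0.16 CPM (-6.45 ± 1.01, adjusted p = 0.00584; -6.52 ± 1.01, adjusted p = 0.0256). Coeloconic receptors were lower as a list against wild type (adjusted p = 2.08e-06; adjusted p = 0.0243 with an estimated correlation) and against heterozygotes (adjusted p = 1.81e-06; adjusted p = 0.0243 with an estimated correlation). Over all genes 4 and 1 of the 10 were lower, and 5 in each case adjusted over the list alone, with 1 higher against heterozygotes. Without mutant library 1, 0 passed over all genes and the list was again called lower (adjusted p = 0.000269 and 0.000805). Palp receptors were lower against wild type (adjusted p = 4.19e-07; adjusted p = 0.00989 with an estimated correlation) and against heterozygotes (adjusted p = 4.01e-06; adjusted p = 0.0191 with an estimated correlation). In both cases 1 of 4 passed over all genes and 2 adjusted over the list alone. The palp is another organ than the antenna, so a differing share of palp tissue between samples could lower these receptors, Or46a included. That was not tested. Among factors of olfactory neuron fate, lozenge (lz), a Runx transcription factor, had 1 count in the mutant. Wild type stood at 0.94 CPM (ratio 24.2, counting interval 3.96 to 993, adjusted p = 0.00375) and heterozygotes at 1.54 (ratio 39.2, counting interval 6.69 to 1580, adjusted p = 0.0019). That list was lower against heterozygotes (adjusted p = 0.0192; adjusted p = 0.593 with an estimated correlation; 1 of 14 over all genes), and not without mutant library 1 (adjusted p = 0.124). Or43a, Or46a and Ir92a passed against both controls in 10, 4 and 4 of 13 alternatives. Or19a, Or19b and lz lost the call without mutant library 1, where lz had an adjusted p of 0.0722 against wild type and 0.0717 against heterozygotes.

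**Figure D3:**
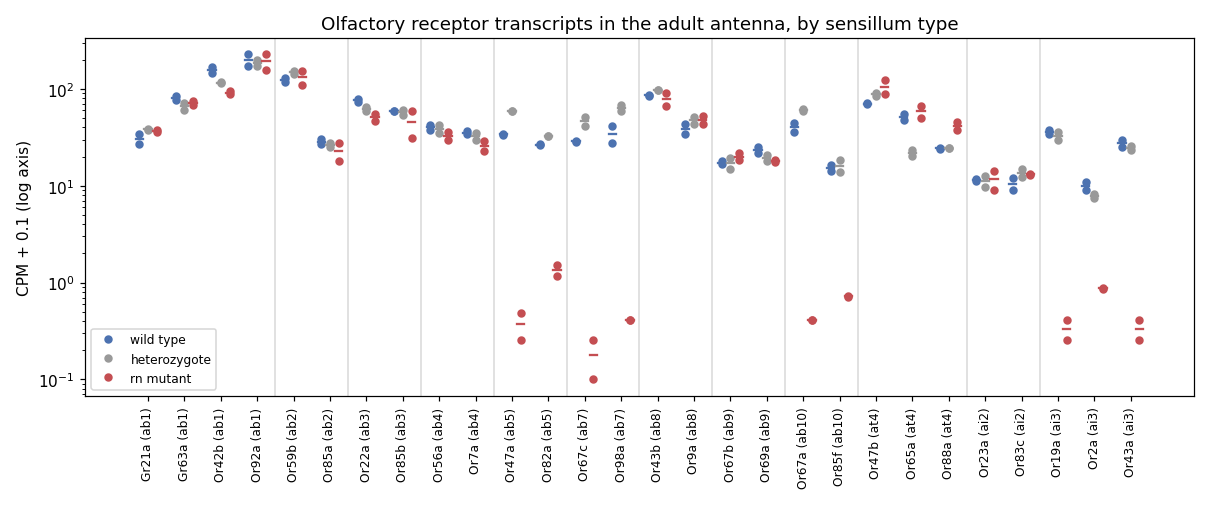
CPM plus 0.1 on a log axis for odorant receptors in the adult antenna, grouped by sensillum, with 1 point per library and colour for genotype. Mutant points for Or67c, Or47a and Or98a lie at or below 0.311 CPM on average, where controls average 28.6 CPM or more, while Or92a and Or59b overlap or lie close to their controls.

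Outside the receptors, Ldh, lactate dehydrogenase, was higher in the adult mutant, at 357 and 194.4 CPM in the 2 libraries against 34.7 ± 1.18 in wild type and 14.4 ± 4.68 in heterozygotes. The changes were 2.99 ± 0.53 (adjusted p = 0.00345) and 4.26 ± 0.56 (adjusted p = 0.000925). MFS3, a member of a transporter superfamily, was at 49.1 ± 22.9 CPM against 4.33 ± 1.07 and 2.17 ± 0.32, and CG34138 at 90.1 ± 12.9 CPM against 1.61 and 8.55. JhI-21, an amino acid transporter, and Bdp1, a subunit of the RNA polymerase factor TFIIIB, were higher by less. JhI-21 was at 5.78, 5.89 and 12.4 ± 1.75 CPM and Bdp1 at 18.3, 21.3 and 39 ± 1.69 CPM. Dgp-1 rose to 132 ± 58.2 CPM from 44.8 ± 5.04 and 46.8 ± 2.57, and CG5697 stood at 0.79, 1.25 and 12 ± 1.92 CPM. CG34034, with 0 counts in wild type, was at least 64.5-fold higher in mutants. CG8483 was at 1.06 and 0.66 CPM in the controls and at 93.36 and 3.147 CPM in mutant libraries 1 and 2, and without library 1 its call was lost (adjusted p = 0.634 against wild type and 1 against heterozygotes). Ugt35C1, a glycosyltransferase, was lower at 17.7 CPM against 172 and 90.1, as were CG8032 (15.5 against 87 and 51.4), CG42766 (0.85 against 18.4 and 19.6) and Map205 (3.03 against 77 and 34.7). CG42766 (X 15976868 to 15977660) lies next to the receptor gene Or13a (X 15974425 to 15976706), which was lower too. Whether its counts hold reads of Or13a was not tested. JhI-21, CG8483, CG34034 and CG42766 passed in 5, 5, 8 and 9 of 13 alternatives, Ldh, Dgp-1, Bdp1 and Ugt35C1 in 10, CG5697 in 12, and MFS3, CG34138, CG8032 and Map205 in all.

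Heat shock genes were higher in the adult mutant than in wild type (adjusted p = 5.54e-13; adjusted p = 0.393 with an estimated correlation), with 6 of 15 past the test over all genes and 15 adjusted over the list alone, and their replicates lay far apart. Hsp23 stood at 1468 and 348.1 CPM in the mutant libraries and at 37.6 ± 28 CPM in wild type, with 676 ± 603 in heterozygotes. Antimicrobial peptides were higher (adjusted p = 0.0153; adjusted p = 0.712 with an estimated correlation), 1 of 13 over all genes and 3 adjusted over the list alone. Dro was at 0.30, 9.99 and 9.02 CPM in wild type, heterozygotes and mutants, and without any of the 4 libraries compared its adjusted p against wild type was 0.0896 to 0.361. Chemosensory coreceptors were lower (adjusted p = 0.00769; adjusted p = 0.305 with an estimated correlation), 1 of 5 over all genes and 1 adjusted over the list alone. Against heterozygotes, fat body genes were higher (adjusted p = 2.52e-08; adjusted p = 0.144 with an estimated correlation), 0 of 8 over all genes in edgeR and 5 adjusted over the list alone. Muscle genes were higher (adjusted p = 0.0176; adjusted p = 0.838 with an estimated correlation) and eye genes lower (adjusted p = 0.0176; adjusted p = 0.699 with an estimated correlation). Camera called none of the ecdysone response, glial, leg and homeotic, pan-neuronal, larval receptor, proximodistal patterning, sex-biased and proneural and Notch lists in the 8 mutant comparisons. Mutant library 1 held 251.2 CPM of the yolk protein gene Yp1 where library 2 held 35.96. Without it, heat shock genes against wild type had 2 members past the test and a median of 1.20 in place of 3.18 (adjusted p = 2.42e-06). The coreceptor (adjusted p = 0.0574), muscle (adjusted p = 0.818) and eye calls (adjusted p = 0.164) were lost, and heat shock genes (adjusted p = 2.66e-11) and sex-biased genes (adjusted p = 0.0488) were called lower than in heterozygotes. Across all genes, 210 were higher and 129 lower than in wild type, and 11 higher and 21 lower than in heterozygotes. The 339 against wild type were 151 and 134 without wild type library 1 or 2 and 145 and 225 without mutant library 1 or 2. The 32 against heterozygotes were 16 without heterozygote library 1 or mutant library 1 and 53 without mutant library 2. The 27 genes against both controls became 15 without heterozygote library 1, 16 without mutant library 1 and 42 without mutant library 2.

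Heterozygotes differed from wild type at many of the genes that differed between mutants and wild type. In the larva, Tektin-C, a protein of sperm flagella, was at 92.2 ± 3.5 CPM in wild type, 0.31 in heterozygotes and 0.27 in mutants, and ppk13, an ion channel subunit, had 0 counts in wild type and 23.5 and 27.6 CPM in the others (at least 189-fold and 221-fold). In the adult, DIP-alpha, a neuronal surface protein, was at 74.4 ± 14.4, 2.79 and 2.62 CPM, and the serotonin receptor 5-HT2A at 62.9 ± 3.45, 0.80 and 1.67 CPM. At 8 h Spn47C was at 1.35, 71.7 and 66.2 CPM, and at 40 h CG3984 at 0.42, 66.4 and 82.1 CPM. Genes that passed against wild type in the same direction in heterozygotes and mutants numbered 59 higher and 50 lower in the larva, 77 and 146 at 8 h, 60 and 34 at 40 h and 110 and 52 in the adult. Independent calls would give at most 7.08, and 0 genes passed in opposite directions in edgeR. The shared wild type libraries alone also tie these comparisons: the correlation of log2 changes across genes was 0.635 to 0.702, and 0.487 to 0.518 on average in counts simulated without an effect, in which genes are not independent replicates.

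By list, 8 of 28 axon guidance genes were lower in heterozygotes than in wild type at 8 h, and 1 without wild type library 1. Among odorant-binding and support-cell genes 3 of 15 were higher at that stage, and 0 without that library. There 2 of 10 coeloconic receptors were lower, among them Ir75a at 14.4 CPM in wild type, 1.91 in heterozygotes and 6.82 in mutants, and 1 was without that library. In the adult 5 of 15 heat shock genes were higher. In the larva 2 of 9 hemocyte genes were lower and 2 of 10 pan-neuronal genes higher, and 0 and 1 without heterozygote library 1. Heterozygotes against wild type gave 104 higher and 100 lower genes in the larva, 137 and 297 at 8 h, 69 and 43 at 40 h and 134 and 66 in the adult. In the larva the total of 204 was 75 without wild type library 2, and 89 and 727 without heterozygote library 1 or 2. At 8 h the total of 434 was 147 and 4824 without wild type library 1 or 2, with 70 higher and 77 lower in the first case, and 161 and 213 without heterozygote library 1 or 2. At 40 h the 112 genes were 50 and 45 without wild type library 1 or 2. In the adult the 200 genes were 77 and 81 without wild type library 1 or 2, and 88 and 97 without heterozygote library 1 or 2.

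**Figure D4:**
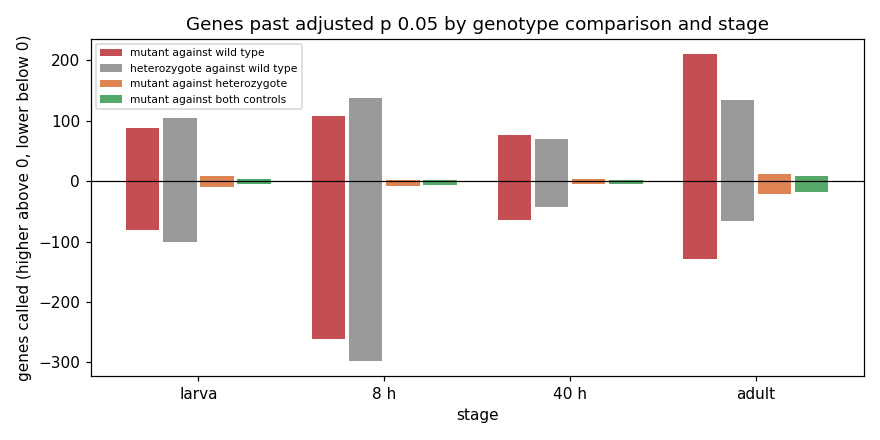
Genes past an adjusted p of 0.05 in edgeR (vertical axis, number of genes, higher above 0 and lower below 0) by stage (horizontal axis), with 1 bar per direction for each genotype comparison. In the adult, 210 genes were higher and 129 lower in mutants than in wild type, 134 and 66 in heterozygotes than in wild type, and 9 and 18 in mutants than in both controls.

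From larva to 8 h in wild type, genes of neuronal wiring and of the ecdysone response changed. Axon guidance genes rose (20 of 28, 1 lower), as did dpr and DIP genes (17 of 30, 2 lower), pan-neuronal genes (7 of 10), glial genes (4 of 8) and proneural and Notch genes (9 of 18, 1 lower). The proneural factor amos was at 0.38 CPM in the larva and 110.5 at 8 h, and the sensory precursor factor sens at 14.3 and 152 CPM (3.41 ± 0.46). The ecdysone response genes Eip93F (1.46 to 854 CPM; 9.18 ± 0.67, adjusted p = 2.66e-08) and ftz-f1 (28.1 to 978 CPM; 5.12 ± 0.31, adjusted p = 2.97e-09) rose and br (1320 to 151 CPM; -3.13 ± 0.28) fell, with 4 higher and 4 lower of 10. Cuticle genes were higher in 48 and lower in 12 of 86. Proximodistal patterning factors were higher in 4 and lower in 7 of 23, and 3 of 4 leg and homeotic genes were lower, with Lim1 from 73 to 9.48 CPM and tsh from 99.4 to 21.6 CPM. Muscle genes were lower in 5 and higher in 1 of 13, eye genes higher in 3 of 14, and 0 of 6 larval receptors passed in edgeR. Without 8 h wild type library 1, 14 axon guidance genes rose and 2 fell, with a median of 0.57 in place of 1.17, 6 pan-neuronal genes rose, 15 dpr and DIP genes rose and 1 fell, and 1 ecdysone response gene rose and 4 fell. In the same fit 49 cuticle genes rose and 6 fell, 7 proneural and Notch genes rose and 1 fell, and 1 muscle gene rose and 4 fell. In all, 2459 genes were higher and 1867 lower, or 2741 in total without larval wild type library 2.

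From 8 h to 40 h, every one of the 21 cell cycle genes fell, among them the mitotic kinase polo (489 to 2.53 CPM; -7.59 ± 0.42) and the replication factors Mcm5 (120 to 0.87 CPM) and PCNA (177 to 1.6 CPM). Proneural and Notch genes fell in 14 and rose in 2 of 18, with sens from 152 to 0.28 CPM (-9.03 ± 0.7). Genes of mature neurons rose: 9 of 10 pan-neuronal genes, among them the sodium channel para (3.73 to 129 CPM; 5.11 ± 0.38) and the synaptic protein Syt1 (3.13 to 59 CPM). So did 22 of 30 dpr and DIP genes with 1 lower, 15 of 28 axon guidance genes with 4 lower, and 4 of 5 coreceptors, with Ir25a from 5.7 to 109 CPM. The transcription factors fru (5.61 to 756 CPM; 7.12 ± 0.45) and pdm3 (25.2 to 375 CPM) rose. Muscle genes rose in 9 and fell in 1 of 13, and eye genes fell in 7 and rose in 1 of 14. Without 8 h wild type library 1, 19 axon guidance genes rose and 1 fell, with a median of 0.91 in place of 0.57, and 23 dpr and DIP genes rose and 1 fell. Then 1 proneural and Notch gene rose and 14 fell, 8 muscle genes rose and 1 fell, and 1 eye gene rose and 6 fell. In all, 2954 genes were higher and 3075 lower.

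From 40 h to the adult, chemosensory genes rose nearly without exception. All 9 receptors of ab1 to ab3, 15 of 16 of ab4 to ab10, 13 of 13 of trichoid and intermediate sensilla, 10 of 10 coeloconic receptors and 5 of 5 coreceptors were higher, with Orco from 8.73 to 2450 CPM (8.13 ± 0.34, adjusted p = 1.25e-11). Among the rest, 5 of 6 arista and sacculus receptors rose and 1 fell, and 3 of 4 palp and 3 of 6 larval receptors rose. Odorant-binding and support-cell genes rose in 14 and fell in 1 of 15, with Obp19d from 31.5 to 20700 CPM. Axon guidance genes fell in 24 of 28, among them the adhesion proteins hbs (409.5 to 8.37 CPM; -5.61 ± 0.19) and Fas3 (619 to 19.7 CPM), and ecdysone response genes in 8 of 10 with 2 higher. Sex-biased genes rose in 5 of 6, with Yp1 from 0.23 to 31.9 CPM. fru fell from 756 to 34.5 CPM, and lz from 6.83 to 0.94 CPM (-2.85 ± 0.38). In all 3165 genes were higher and 2836 lower.

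Between larva and 8 h the mutant effect against wild type differed for 31 genes, 10 with a higher and 21 with a lower effect at 8 h, and between 40 h and the adult for 82 genes, 53 and 29. CHKov1 was 1 of them: in mutants and wild type it stood at 0.48 and 112 CPM at 40 h and at 139 and 50.2 CPM in the adult. The MFS3 values were 16.4 and 26.6 CPM at 40 h and 49.1 and 4.33 CPM in the adult. For Nlg1, a neuroligin, the values were 4.15 and 0.97 CPM in the larva and 20.3 and 43.2 CPM at 8 h. The early count was 12 and 4 without larval wild type library 1 or 2, 5 and 4 without larval mutant library 1 or 2, 13 and 3404 without 8 h wild type library 1 or 2, and 3 and 18 without 8 h mutant library 1 or 2. The late count was 23 and 38 without 40 h wild type library 1 or 2, and 49 and 23 without 40 h mutant library 1 or 2. It was 31 and 32 without adult wild type library 1 or 2, and 45 without adult mutant library 1. With only the libraries of those stages, edgeR called 0 genes for the mutant effect at 8 h against mutant effect at larva. At an unadjusted p under 0.05 that fit held 449 genes, and DESeq2 with all libraries called 96.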

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

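Of the tests below, those of chromosome arm, of rn level, of dose with split wild type libraries, of the spread of tissue lists and of transcript length were chosen after the results were seen. Differences of the mutant effect between stages are log2 differences ± SE in edgeR, with CPM in mutants and wild type.

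Of 31 genes whose mutant effect differed between larva and 8 h, the 5 with the smallest p-values are given. CG42272 had a difference of 2.401 ± 0.282 (adjusted p = 0.00203), with 5.47 and 38.7 CPM in the larva and 57.9 and 77.2 at 8 h. The difference for CG14082 was -7.593 ± 0.919 (adjusted p = 0.00203), a fitted value that rests on a wild type larval level of 0, with 1.64 CPM in larval mutants. In Oseg5 it was 3.612 ± 0.453 (adjusted p = 0.00203), with 0.709 and 18.6 CPM in the larva and 17 and 35.9 at 8 h. Nlg1 differed by -3.142 ± 0.447 (adjusted p = 0.0074), and CG15905 by 3.86 ± 0.606 (adjusted p = 0.0232). With only the libraries of these stages the adjusted p of the 5 genes lay between 0.0742 and 0.284. The call for Nlg1 was also lost without larval mutant library 2 (adjusted p = 0.0547) and without 8 h mutant library 1 (adjusted p = 0.0633). CG15905 lost its call without larval wild type library 1 (adjusted p = 0.0541) or 2 (0.0695), larval mutant library 1 (0.103) or 2 (0.0726), or 8 h mutant library 1 (0.0725).

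Between 40 h and the adult the effect differed for 82 genes, and the 5 with the smallest p-values each differed under every alternative run. CHKov1 went from far lower to higher in mutants, a difference of 9.289 ± 0.534 (adjusted p = 7.83e-08). CG14275 differed by -5.636 ± 0.465 (adjusted p = 9.01e-06), with 28.5 and 0.973 CPM at 40 h and 64.2 and 110.4 in the adult. For CG7900 the difference was 4.848 ± 0.51 (adjusted p = 0.00019), with 1.64 and 2.23 CPM at 40 h and 253 and 11.9 in the adult. MFS3 differed by 4.195 ± 0.474 (adjusted p = 0.000381). CG17549 differed by -3.035 ± 0.354 (adjusted p = 0.000454), with 19.7 and 4.01 CPM at 40 h and 68.2 and 114 in the adult.

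Genes that separated mutants from both controls before adulthood, such as Map205, CHKov1 and Calx, lay mostly on the chromosome arm of rn: 8 of 13 genes (61.5%, exact 95% interval 31.6 to 86.1) were on 3R, against 24.9% of the other tested genes (Fisher exact p = 0.00555, two-sided). Of the 7 genes on 3R found in the larva or at 8 h, Map205, GstZ1, CHKov1 and CG5697 passed again at 40 h (GstZ1 in 6 of 13 alternatives), where rn was low. That goes against regulation that follows the level of rn mRNA, for these 4 only. Their log2 changes against wild type there were 4.88 or more in the earlier direction. Since they were picked because they passed at 40 h, the size of those changes is no separate test. Such regulation stays open for Calx, CG34353 and ATPsynepsilonL, whose median change at 40 h, signed by the earlier direction, was -0.02 (-2.53 to 0.72). For the 4 genes elsewhere, Ac3, CG9008, CG3726 and CG34461, that median was 0.04 (-0.04 to 0.41). A dependence on rn level would give this, but so would any other difference limited to the early stages. These 4 genes had negative log2 changes in mutants against wild type in the larva and at 8 h. Mean rn mRNA in mutants and wild type was 71.7 and 43.2 CPM in the larva and 46.7 and 103 at 8 h. Their change thus did not track rn mRNA in the mutant, and what rn[tot] does to that mRNA is not given. Variants linked to the rn allele stay open as a candidate source for the genes on 3R, and dependence on rn that outlasts its mRNA was not tested.

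Many more genes separated heterozygotes from wild type, such as Tektin-C and DIP-alpha, than mutants from heterozygotes, for example 204 against 18 in the larva and 200 against 32 in the adult. Differences confined to the third chromosome, which carries rn, were judged on 11 genes, among them Spn47C, CG34138 and didum. These were called in the same direction in both comparisons with wild type at all 4 stages. Of them 45.5% lay there (exact 95% interval 16.7 to 76.6), against 44.7% of the other genes, which argues against that explanation for these genes only. Effects of TM6 cannot be judged this way, since mutants lack TM6 and each gene had to differ in mutants too. Dose of functional rn copies would place the heterozygote midway and stays open, since the median ratio of the heterozygote to the mutant log2 change, 0.79 or more at each stage, is pulled up by the wild type libraries that both changes share. With a different wild type library in each change that ratio was 0.67 to 0.84 in the larva, at 40 h and in the adult and 0.06 and 0.83 at 8 h. It was 0.55 to 0.71 outside 8 h when higher genes were compared on the linear scale and lower genes stayed on the log2 scale. For lower genes the log2 scale gives a smaller ratio than the linear scale would. Picking genes by their mutant change also pulls the ratio down. These ratios therefore cannot decide whether the heterozygote lies midway. A difference of genetic background between the wild type and the rn stock was not tested and stays open.

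Wild type library 1 at 8 h stood apart from the other 8 h libraries, with the long transcripts of CadN and other axon guidance genes high. RpL35A was at 12.8 CPM and RpL8 at 28.7 CPM, against 900 and 1820 in library 2. These 2 were picked among the genes furthest from the other 8 h libraries, and ribosomal protein genes were not tested as a list. Both were also low in larval heterozygote library 1, at 40.2 and 95.4 CPM against 1220 and 2300 in its library 2. Nervous tissue stays open, since the median log2 difference from library 2 was 0.72 for 10 pan-neuronal genes (exact interval -0.03 to 1.18) and 0.26 for 6 glial genes (-1.29 to 1.12), and against the other 5 libraries it was 1.10, 0.32 and, for dpr and DIP genes, 0.92. Muscle, fat body and blood cells stay open as well, since their list medians of 0.36, -0.33 and -0.38 rest on genes that moved both ways (-2.42 to 1.39, -2.16 to 1.5 and -2.55 to 2.14). Another developmental time is also open, since the correlation across genes with the heterozygote steps was -0.196 and 0.127, between the bounds set for it. Loss of short transcripts may contribute and cannot be told apart from spread between replicates: Spearman rho with transcript length across genes was 0.284, where the highest of the other replicate pairs reached 0.25.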

How the results depend on the processing

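The sum over transcripts and the omission of the 4 libraries in doubt were chosen after the data were seen. Counts below are genes past the threshold, in the order larva, 8 h, 40 h and adult unless a stage is named, and unless noted the cause of a change was not tested. RLE scaling, no low-count filter and the sum over transcripts left all 21 counts within 1.5 times, and of 568 values of named genes 565, 553 and 531 kept direction and call. DESeq2 left 3 of 21 counts within that range and gave more genes in 18: 294, 1114, 273 and 582 for mutant against wild type, 42, 40, 35 and 86 for mutant against heterozygote, 394, 1201, 215 and 370 for heterozygote against wild type, 19, 18, 16 and 52 for mutant against both controls, and 96 and 232 for the mutant effect at 8 h against mutant effect at larva and at adult against mutant effect at 40 h. With simulated counts DESeq2 made 27 false calls and edgeR 4, but their spread came from the edgeR fit, so this does not rank the tools on these data. With only the libraries of the stages compared, 10 counts fell and 5 rose. This setting leaves fewer residual degrees of freedom, which would not by itself account for the rises. Spread between replicates differed by group, with a chi-squared per degree of freedom from 4.0 in larval mutants to 282.4 in 8 h wild type. Here mutant against wild type gave 47 in the larva, 0 at 8 h (unadjusted 682) and 1311 in the adult, mutant against heterozygote 3, 0 (unadjusted 141) and 159, heterozygote against wild type 28, 0 (unadjusted 727) and 830, both controls 3, 0 and 96, wild type 8 h against larva 2798, and the differences between stages 0 (unadjusted 449) and 233. A replicate block gave 240 for mutant against wild type at 8 h, 11 and 5 for mutant against heterozygote in the larva and at 40 h, and 135, 233 and 72 for heterozygote against wild type in the larva, at 8 h and at 40 h. Without the 4 libraries in doubt 11 counts rose: mutant against wild type to 517 in the larva, 494 at 40 h and 748 in the adult, mutant against heterozygote to 64, 25 and 58 at 8 h, 40 h and adult, heterozygote against wild type to 264 and 825 at 40 h and adult, both controls to 22 and 12 at 8 h and 40 h, and the adult against 40 h difference to 264. Leaving out 1 library at a time, with the lone library assumed to vary like the other groups, gave these ranges: mutant against wild type 83 to 129, 87 to 4800, 61 to 82 and 134 to 225, mutant against heterozygote 5 to 82, 5 to 49, 3 to 21 and 16 to 53, heterozygote against wild type 75 to 727, 147 to 4824, 45 to 139 and 77 to 97, both controls 3 to 12, 4 to 15, 3 to 7 and 15 to 42, wild type steps 2741 to 6061, 4982 to 6753 and 4809 to 4970, and differences between stages 3 to 3404 and 23 to 100. The highest 8 h values of the comparisons with wild type came without wild type library 2, which leaves wild type library 1 alone, and that of mutant against heterozygote without heterozygote library 2. Sxl, 0.77 for wild type 8 h against larva, was -0.055 without 8 h wild type library 1, 1.295 without library 2 and -0.057 without the 4 libraries in doubt. Of 38 gene list calls, 10 held with an estimated correlation, while 37 were made with RLE scaling and 27 without the 4 libraries. Named values kept direction but not the call in 132 of 551 cases with only the stages' libraries, in 69 of 568 with the block, in 62 of 568 without the 4 libraries and in 515 of 2312 leaving out 1 library. Depth limits genes such as lz, Or49a and Or42a, whose mutant levels are at or near 0.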

Other observations

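The tests of receptors by sensillum and those of the adult receptor losses were chosen after the results were seen.

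Some receptors of the adult antenna fell short of the thresholds, and those given here were chosen after their values were seen. Or42a, a receptor of the palp, stood at 3.46 CPM in wild type, 4.09 in heterozygotes and 0.155 in mutants (edgeR adjusted p = 0.0559 and 0.227), and Or49a at 0.83 and 0.78 CPM in the controls with 0 counts in mutants, at least 7.09-fold and 6.81-fold lower. Ir84a, the coeloconic receptor for food-derived aromatics, was at 18.3, 18.9 and 2.34 CPM (-2.96 ± 0.59 against wild type, adjusted p = 0.0106; -3.01 ± 0.59 against heterozygotes, adjusted p = 0.0515). Its call against wild type was lost without any of the 4 libraries compared, at adjusted p between 0.0526 and 0.177. The receptors of sensillum at4, Or47b, Or65a and Or88a, did not pass in mutants against heterozygotes. Their levels there were 105.5, 58.6 and 41.1 CPM in mutants and 87.8, 21.7 and 24.6 in heterozygotes.

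A hypothesis from these data is that receptors in the neurons of 1 sensillum type tend to be lost or kept together in the rn mutant. Of 12 sensilla with 28 receptors at 5 CPM or more in both controls, 3 had each receptor below 10% of the heterozygote level: ab5 (Or82a, Or47a), ab7 (Or98a, Or67c) and ab10 (Or67a, Or85f). In 8 sensilla no receptor was below it, and in ai3 Or19a and Or43a were while Or2a stood at 10.1%. The mean log2 difference between receptors within a sensillum was 0.93, against a median of 3.4 when receptors were shuffled among sensilla (one-sided permutation p = 0.00018, 100000 permutations), which is consistent with loss by sensillum, for receptors assigned to sensilla from general knowledge. That set left out Or33b of ab5, low in wild type, as well as paralogs, ab6 and the coeloconic sensilla. Over 44 receptors in 17 sensilla at 5 CPM or more in heterozygotes, with these included, 2 sensilla lost each receptor, 11 lost none and 4 were mixed. In the mixed ones Or33b stood at 99.4% of the heterozygote level in ab5, Or49b at 80.1% beside Or13a at 2.61% in ab6, Ir31a at 52.2% beside Ir92a at 5.74% in ac1, and Or2a at 10.1% in ai3. The mean difference within a sensillum was 1.23 there, against a shuffled median of 3.11 (permutation p = 2e-05, which paralogs that share reads make smaller), so the tendency held over this set with exceptions. A loss of the neurons and a loss of receptor transcription within them would look alike here.

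Fewer neurons of every olfactory class are argued against as the whole source of the receptor losses: of all 48 listed receptors at 5 CPM or more, passing or not, 66.7% had a log2 change against heterozygotes above -1 (exact 95% interval 51.6 to 79.6, for receptors taken as independent, against a bound of 50%). Their median change was -0.32 (-9.03 to 1.43), and a smaller general loss was not excluded. For the set of 14 genes (13 receptors and lz), position bears only on sequence variants linked to the rn allele in or near these genes. Such variants are argued against for the set, since 71.4% of it lay off 3R (Fisher exact p = 0.759 for its share on 3R). They could still account for single genes on that arm such as Or98a. A linked variant in another gene that acts on these genes would not show by position and was not tested. The other adult genes that differed from both controls were left out of this test. Of them Map205, CG8032, CG8483, CG5697, Ugt35C1, CG34034 and CG34138 lay on 3R, and Ldh, Dgp-1, JhI-21, MFS3, Bdp1 and CG42766 elsewhere. Linked variants stay open for those on 3R.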
